A study of Mus musculus with 5 samples.

How the data were processed

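Single-cell RNA was measured with the 10x Genomics droplet method in 5 libraries of dendritic cells (DCs) sorted from mouse lymph nodes as lineage-negative, CD11c-positive and MHC class II-high cells. Per the labels, 2 libraries came from tumor-draining inguinal nodes and 2 from non-draining axillary nodes of mice in which melanomas (activated BRAF, loss of PTEN) had been induced 4 weeks earlier, and 1 came from the inguinal node of tumor-free wildtype mice. The number of mice behind each library is not given in the sources used here. Nothing in them says that the libraries come from separate animals or that equal replicate numbers share one, so every p-value measures only the spread between these samples, which may be technical. Draining and control nodes were inguinal and non-draining nodes axillary, so the tumor's drainage and the anatomical site of the node were not separated in the comparison of draining with non-draining nodes.

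The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, made by the authors with Cell Ranger 3.1 on the mm10 genome, per the submitters' processing notes. Their settings, and any correction for free RNA, are not given in the sources used here. The values were checked to be whole numbers with totals that differed between cells. Of 31053 features, 30934 (99.62%) were found in GENCODE vM21 (GRCm38), which gave the positions.

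The lowest barcode began with AAACCTG in draining and non-draining replicate 1 and with AAACCCA in the other 3 libraries, although the labels list one kit (chemistry 3.1) for all 5. The largest clusters of plasmacytoid DCs, of B cells and of T cells split along the same line, while other T cell clusters held cells of both barcode sets. This barcode set coincides with the replicate number, so a fit with the replicate as a block, planned as an alternative, also takes out the barcode set. It is given first in the comparison of node groups, because several clusters held cells of one barcode set almost alone, and the planned fit without a block stands beside it. Leading with it was decided after the data were seen, as was adding the barcode set as a term to the comparisons with the control, which shares its set with both replicate 2 libraries.

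Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept, 8868 of 9649. Clustering used Python 3.11.15, scanpy 1.11.5 and leidenalg 0.10.2 on counts scaled to 10000 per cell and log-transformed. It took 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours and Leiden resolution 1, with no integration. All genes of the tested and technical lists, and mitochondrial, ribosomal, immunoglobulin and T cell receptor genes, were left out of the clustering. A cluster took the name of the cell type with the most markers at least 3-fold above the other cells and at 50 CPM or more (UMI counts scaled to a common library total), with at least 3 such markers. This named 33 of 35 clusters and left 160 cells unnamed. Classes are called cDC1-like (cross-presenting conventional DCs), cDC2-like, mregDC-like (mature, migratory DCs with Ccr7, Fscn1, Ccl22 and Relb) and so on, since markers alone named them. Ccl22 and Ccl17 are among the mregDC markers, and Ccl22, Ccl17, Fabp5, Crispld2 and Myl7 were leading genes of cluster 7, so these genes partly define the class or a cluster. Cluster 30 (49 cells) carried B cell markers along with the macrophage genes Apoe and C1qa, and whether it holds mixed droplets stays open. No B cell comparison was made. Scrublet called 125 cells (1.41%) doublets, kept in the main analysis.

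UMI counts were summed per library over all kept cells or over a class, with at least 20 cells per sum. Tests used edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood test) with Benjamini-Hochberg adjustment and a threshold of 0.05, and DESeq2 1.42.0 beside it. Values per library are CPM. Log2 fold changes are edgeR estimates with the standard error (SE) implied by the test. The fit without a block had 2 residual degrees of freedom, from the groups with 2 libraries, and the lone control was assumed to vary like them. The fit with the block left the control out and had 1, so its test leans on a spread shared across genes. Comparisons of classes took 1 sum per class and library with the library as a block. For the parts of the mregDC-like class with and without a Cd63 UMI, each cell was first thinned to 2000 UMIs, so that depth did not set detection, and cells under that depth were left out. In the test of whether the node effect differed between classes, both classes came from draining and non-draining nodes with the library as a block.

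Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted by Benjamini-Hochberg over the 12 lists. With an estimated correlation camera uses the residual degrees of freedom, 1 or 2 between groups and 4 between classes, and has little power. Unfolded protein response genes in mregDC-like cells between nodes, with the block, had an estimated correlation of -0.018, yet adjusted p = 0.581. Losing a call under it therefore does not show that correlation between genes made the call. They cover cholesterol synthesis, SREBF2 regulation and cholesterol uptake, fatty acid synthesis, cholesterol efflux under the LXR receptors, glycolysis and lactate, tolerance and immunoregulation, costimulation, the interferon response, MHC class I, MHC class II, NF-kB inflammation and the unfolded protein response. Technical lists (tissue dissociation stress, proliferation, sex-linked genes and melanocyte genes) and cell type markers were read as levels. No list was chosen by the study on these samples. Lists, classes, comparisons, tests and the other settings listed below, except the barcode set as a term, were chosen before the data were examined.

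The text names genes by a rule fixed at the same time. Between groups it takes up to 10 genes with the largest rise and up to 10 with the largest fall past the threshold, at an average log2 CPM of at least 4 and with every library of one group above every library of the other, without immunoglobulin, T cell receptor, ribosomal, mitochondrial, Gm- and Rik-named genes. It adds up to 3 members of each tested list with the smallest p. Between classes it takes up to 12 cholesterol synthesis genes and up to 4 of each other list. Cd63, Srebf2, Hmgcr and Ldlr are always included. Genes outside the rule are named as such.

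Shares of cells carry exact binomial 95% intervals (Clopper-Pearson, scipy 1.17.1), which cover counting error only, and were compared with an exact permutation test. Total depth ran from 8528411 to 21517610 UMIs per library. Tested on simulated data in which 200 genes were changed 2-fold, the fit without a block recovered 3 (1.5%) over all cells and 2 in the mregDC-like class, and the fit with the block 191 (95.5%) and 98 (49%). At 4-fold these became 168 (84%) and 139 (69.5%) without the block, and 200 and 189 (94.5%) with it. At 2-fold the fit with the block also called 9 and 7 unchanged genes, and DESeq2 with the block recovered 141 and 29. Every simulated gene had the spread of the trend shared across genes, on which the fit with the block leans. Its recovery on genes with their own spread is therefore not shown. The comparisons of classes recovered 191 and 192 at 2-fold, and the tests of a difference in node effect 21 and 42. A list shifted in the simulation passed camera, with 0 of the 11 others.

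Alternatives were DESeq2, size factors from DESeq2 in edgeR, no low-count filter, the block, leaving out the control or each library, no cell filter, doublets removed, only the 3 conventional DC classes, Leiden resolution 2, classes from a marker score, counts thinned to the smallest library, an estimated correlation in camera, no library block, and thinning to 1000 UMIs or none. Other data types that the series describes were not analysed here.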

Results

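UMI counts of 5 libraries were analysed, in 3 groups: tumor-draining nodes (n = 2), non-draining nodes (n = 2) and a control node (n = 1, no replicate). The matrices held 2246 and 1459 cells with 11626146 and 10726865 UMIs for the draining replicates 1 and 2. They held 2253 and 1013 cells with 10800889 and 8528411 UMIs for the non-draining replicates, and 2678 cells with 21517610 UMIs for the control. Median depth of the kept cells was 4595 and 4817 UMIs in draining and non-draining replicate 1, 6383 and 7324 in replicate 2, and 7606.5 in the control. Depth followed the barcode set more than the node, and within each set it was higher in the non-draining than in the draining library.

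The first question was which cells the sorted fraction held in each node. mregDC-like cells, the mature migratory DCs that carry Ccr7 and Fscn1, made up 24.71% (507 cells) and 20.17% (287 cells) of the draining libraries. They made up 6.28% (113 cells) and 12.83% (125 cells) of the non-draining libraries and 20.46% (536 cells) of the control. Plasmacytoid DC-like cells, which carry Siglech and are known as interferon producers, were 14.08% and 10.33% in draining, 29.46% and 17.76% in non-draining and 37.37% in control nodes. cDC1-like cells were 14.23% and 4.71% in draining, 13.34% and 6.26% in non-draining and 6.26% in control nodes, and cDC2-like cells 6.68% and 3.94%, 6.56% and 5.85%, and 11.72%. T cell-like cells took 20.13% and 34.08% of the draining, 19.73% and 26.18% of the non-draining and 8.89% of the control library, although the sort was lineage-negative, and B cell-like cells 10.09% and 19.18%, 9.12% and 19.1%, and 7.9%. NK and innate lymphoid-like cells were 5.36% and 4.22% in draining, 9.95% and 7.6% in non-draining and 3.7% in control nodes.

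The mean mregDC-like share was 22.44% ± 3.21 (SD, n = 2) in draining and 9.55% ± 4.63 (SD, n = 2) in non-draining nodes. The difference of 12.89 percentage points was larger than the spread between replicates, and within the barcode sets it was 18.43 and 7.34. A two-sided exact permutation test of the share gave p = 0.33, the smallest that 2 against 2 libraries allow. The control share lay within the 95% interval of draining replicate 2 (18.11% to 22.35%). Within the class, the cluster with the highest Ccl22 and Ccl17, chemokines that attract CCR4-bearing T cells (cluster 7), held 42% and 25.8% of the draining cells, 11.5% and 1.6% of the non-draining cells and 1.1% of the control cells. Cluster 2, led by Clu and Apol7c, held 7.1% and 41.1% of the draining, 20.4% and 63.2% of the non-draining and 77.4% of the control cells, a split that followed the barcode set as well as the node.

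**Figure D1:**
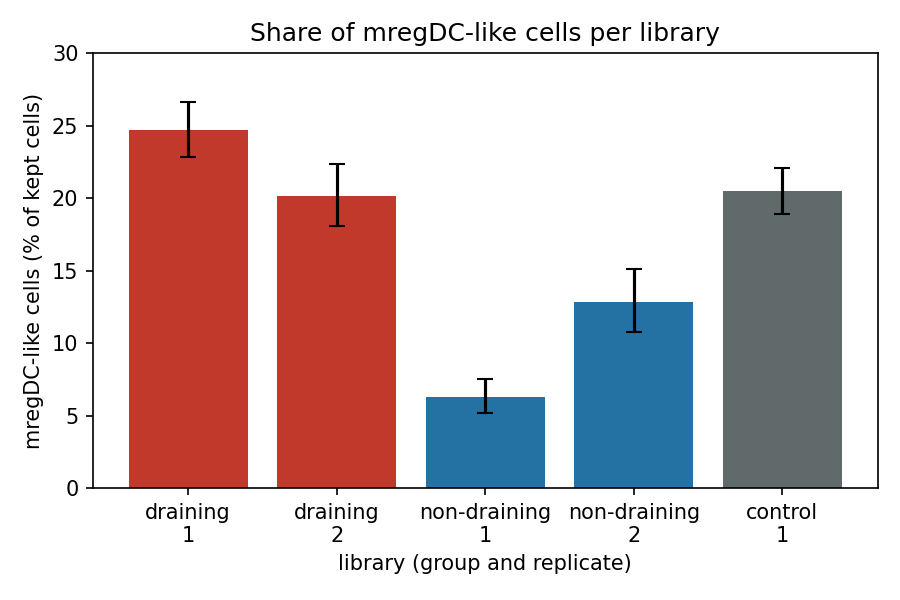
Share of kept cells in the mregDC-like class (%, y axis) in each of the 5 libraries (x axis), with exact binomial 95% intervals as error bars. The draining libraries stood at 24.71% and 20.17%, the non-draining ones at 6.28% and 12.83%, and the control at 20.46%.

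The second question came from the series title, which names SREBF2, the transcription factor that switches on cholesterol synthesis, in a tolerant DC population: do mregDC-like cells express this program above cDC2-like and cDC1-like cells? Idi1 and Hmgcr, genes of the cholesterol synthesis pathway, rose in mregDC-like cells. Idi1, the isomerase of the isoprenoid steps (ENSMUSG00000058258, GRCm38 chromosome 13, 8885501 to 8892451), stood at 173 ± 82.6 CPM (SD, n = 5) against 26.6 ± 20.5 in cDC2-like and 20.2 ± 15.4 in cDC1-like cells. Hmgcr, the rate-limiting enzyme of the pathway (ENSMUSG00000021670, chromosome 13, 96648967 to 96670936), stood at 87.8 ± 51.2 CPM against 29.3 ± 14.4 and 35.2 ± 19.1. The receptor gene Ldlr, through which cells take up cholesterol, rose too, as did Abcg1, which exports it, while Lipa, the lysosomal acid lipase, fell.

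Cholesterol synthesis genes rose in 14 of 15 measured members against cDC2-like cells and 1 fell (Ebp, a sterol isomerase, named after its value was seen). The median log2 fold change was 1.776 (adjusted p = 5.55e-05, camera; adjusted p = 0.369 with an estimated correlation). Against cDC1-like cells 15 of 19 rose and 0 fell, with a median of 1.39 (adjusted p = 0.00118; adjusted p = 0.332 with an estimated correlation). Adjusted over the list alone the counts were the same. Idi1 rose by 2.86 ± 0.2 (log2, SE; adjusted p = 2.48e-08, edgeR) against cDC2-like and by 3.27 ± 0.17 (adjusted p = 2.23e-11) against cDC1-like cells. Hmgcs1, the synthase before Hmgcr, rose by 1.92 ± 0.17 and 2.02 ± 0.14, and Hmgcr by 1.78 ± 0.19 (adjusted p = 2.4e-06) and 1.39 ± 0.13 (adjusted p = 7.33e-08). Cyp51, which demethylates lanosterol, rose by 2.02 ± 0.18 and 2.14 ± 0.16. Ldlr rose by 1.68 ± 0.2 and 2.75 ± 0.19, Abcg1 by 1.67 ± 0.14 and 2.45 ± 0.19, and each of these genes was higher in 5 of 5 libraries. Srebf2 itself (ENSMUSG00000022463, chromosome 15, 82147181 to 82205379) stood at 89.9 ± 17.4 CPM (SD, n = 5) in mregDC-like, 63.5 ± 12.6 in cDC2-like and 74.6 ± 4.95 in cDC1-like cells. It rose by 0.68 ± 0.12 (log2, SE, adjusted p = 0.000326, edgeR) against cDC2-like cells. Against cDC1-like cells Srebf2 was lower in draining replicate 1 (69.4 against 71.4 CPM). It was higher in the other libraries, most in non-draining replicate 2 (117 against 80.3 CPM). Plasmacytoid DC-like cells were not tested against the class. There Idi1 stood at 42.3 ± 21.9 CPM (SD, n = 5), Hmgcr at 40.3 ± 21.2 and Srebf2 at 82.4 ± 12.1. The cholesterol synthesis gene Sqle stood at 23.1 ± 8.1 there and at 26.3 ± 5.8 in mregDC-like cells. Proliferation genes, a list of cell cycle markers, summed to 902 to 1160 CPM in mregDC-like, 509 to 1120 in cDC2-like and 971 to 3610 in cDC1-like cells.

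**Figure D2:**
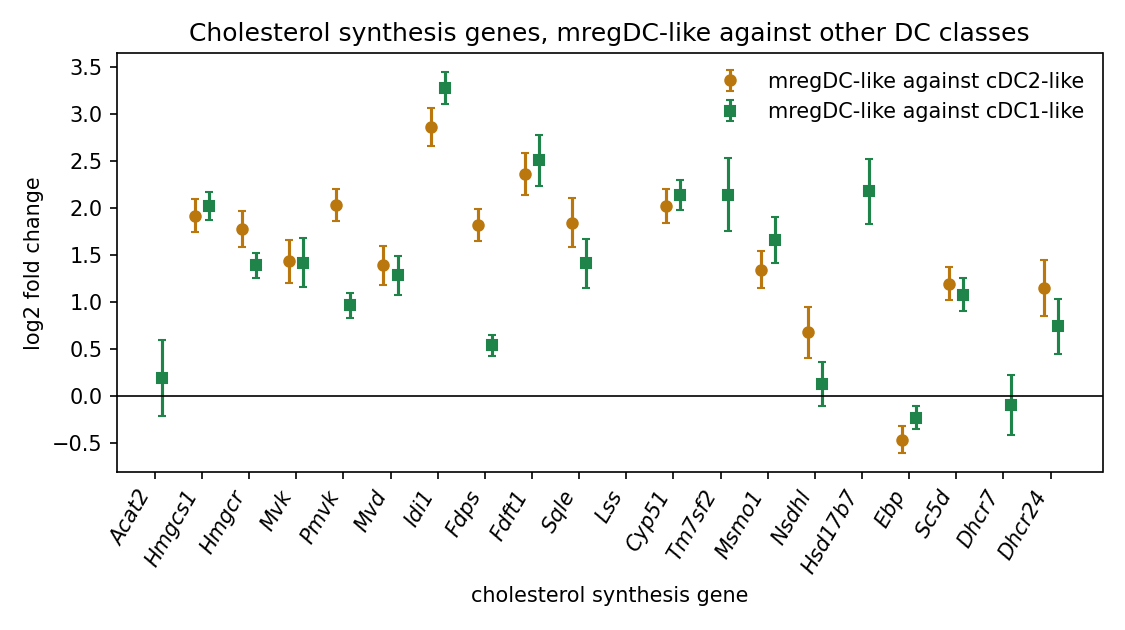
Log2 fold change with its SE (y axis) of each measured cholesterol synthesis gene (x axis) in mregDC-like cells against cDC2-like and against cDC1-like cells, from 5 libraries with the library as a block. Idi1 had 2.86 and 3.27, and the list medians were 1.776 and 1.39.

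Immune gene groups parted in the same comparisons. Costimulation genes, which activate T cells, rose in 8 of 10 members against cDC2-like cells (median log2 fold change 1.998, adjusted p = 1.45e-08; adjusted p = 0.0404 with an estimated correlation) and in 9 of 10 against cDC1-like cells (2.921, adjusted p = 3.28e-09; adjusted p = 0.0957 with an estimated correlation). Tolerance genes rose in 10 of 13 members (1.405, adjusted p = 0.00146; adjusted p = 0.0697 with an estimated correlation) and in 12 of 16 (3.109, adjusted p = 6.65e-05; adjusted p = 0.0957 with an estimated correlation). Among them were Socs2, a brake on cytokine signalling, at 871 ± 132 CPM (SD, n = 5) against 37.2 ± 6.61 and 9.49 ± 10.8, and Cd63, a tetraspanin of late endosomes, at 734 ± 170 CPM against 60.6 ± 17.8 and 6.95 ± 4.12. MHC class I genes rose in 11 of 12 and 9 of 12 members (1.298, adjusted p = 3.33e-07, and 0.826, adjusted p = 0.00183; adjusted p = 0.218 and 0.338 with an estimated correlation). MHC class II genes fell in 12 of 12 and 10 of 12 (-2.445, adjusted p = 3.76e-18, and -2.284, adjusted p = 1.3e-13; adjusted p = 0.0697 and 0.0148 with an estimated correlation). H2-Ab1, a class II chain, fell by 2.74 and 2.69 on the log2 scale. NF-kB genes rose in 9 of 11 and 9 of 12 members (1.562, adjusted p = 0.000793, and 1.592, adjusted p = 3.3e-07; adjusted p = 0.0697 and 0.0957 with an estimated correlation), among them Traf1, an adaptor of TNF receptors. Unfolded protein response genes fell in 8 of 11 in each comparison (-1.557, adjusted p = 0.00858, and -1.823, adjusted p = 0.000207; adjusted p = 0.438 and 0.135 with an estimated correlation), among them the chaperone gene Hspa5. Members of these lists that passed in the other direction, named after their values were seen, were the tolerance genes Tgfb1 (-3.1 and -2.77, log2), Havcr2 (-3.84 and -4.48) and, against cDC1-like cells alone, Lgals9 (-3.29) and Socs3 (-1.97), and the MHC class I list member Calr (-1.1 and -1.28). Against cDC2-like cells the NF-kB genes Il1b (-2.65) and Nfkb1 (-1) fell, and against cDC1-like cells Cd86 (-0.81) fell and the MHC class II list member Ctss (1.08) rose. Of the unfolded protein response genes Ddit3 (1.23 and 1.55) and Dnajb9 (1.16 and 1.7) rose in both comparisons and Atf4 (0.52) against cDC2-like cells, so that list split.

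Glycolysis genes did not pass as a list (median log2 -0.292, adjusted p = 0.149, and -0.502, adjusted p = 0.156), yet 9 and 11 of 18 members fell and 3 and 4 rose. Ldha, which makes lactate, fell by 1.77 and 2.3 on the log2 scale and Hk2, the first enzyme of glycolysis, by 3.7 and 3.42, while Pfkfb3, an activator of glycolysis, rose by 2.85 and 4.14. SREBF2 regulation and uptake genes (0.411, adjusted p = 0.683, and 0.262, adjusted p = 0.557), fatty acid synthesis genes (-0.298, adjusted p = 0.683, and -0.473, adjusted p = 0.437) and interferon genes (-0.151, adjusted p = 0.781, and 0.429, adjusted p = 0.557) did not pass. Cholesterol efflux genes did not pass either. Against cDC2-like cells their median was 0.219 while the test leaned down (adjusted p = 0.716), and against cDC1-like cells the median was -0.342 while the mean, 0.13, and the test leaned up (adjusted p = 0.829). Across all genes, 4047 of 7165 differed from cDC2-like cells (1964 up, 2083 down) and 5735 of 8987 from cDC1-like cells (2893 up, 2842 down), so a call alone does not set a gene apart. Which clusters made up the class differed by barcode set, but both classes of a comparison came from the same library.

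A further question, from background knowledge that CD63 marks part of the mature DCs, was whether the mregDC-like cells with a detected Cd63 UMI (ENSMUSG00000025351, chromosome 10, 128900989 to 128912822) differed from the rest. After thinning to 2000 UMIs per cell, a Cd63 UMI was found in 57.89% (264 of 456 cells) and 69.26% (196 of 283) of the mregDC-like cells of draining, 61% (61 of 100) and 69.42% (84 of 121) of non-draining, and 70.69% (369 of 522) of control nodes. At the same depth of 2000 UMIs it was found in 0.855% to 2.09% of cDC1-like cells and in 5.36%, 6.25%, 9.01%, 1.75% and 9.15% of cDC2-like cells. In plasmacytoid DC-like cells it was in at most 1.07%. Before thinning, the median depths were 4096 and 7607 UMIs in the mregDC-like cells of draining nodes and 5915 and 9300 in the plasmacytoid ones. Without thinning, 72.98% and 93.73% of the mregDC-like cells of draining, 70.8% and 88% of non-draining and 91.79% of control nodes had a Cd63 UMI. Many cells counted as without one thus carried Cd63 RNA, and the parts are not Cd63-positive and Cd63-negative cells. The split also moved by draw: after doublet removal, which took no mregDC-like cell from non-draining replicate 1, it was 53 of 100 there.

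mregDC-like cells with a Cd63 UMI had more RNA of Idi1, Hmgcs1 and Fdps. Idi1 was at 169 ± 93.2 CPM (SD, n = 5) against 91.8 ± 45.9 in the cells without one, and Fdps, which makes farnesyl diphosphate, at 101 ± 37.1 against 56.6 ± 11.4. Il4i1, an enzyme that degrades amino acids and dampens T cells, was at 1080 ± 404 CPM against 630 ± 217. The costimulatory genes Cd83, Icosl and Cd40 and the antigen presentation genes H2-D1, B2m, H2-K1 and Cd74 rose as well.

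Cholesterol synthesis genes were higher in 8 of 8 measured members and 3 rose (4 adjusted over the list alone), with a median of 0.457 (adjusted p = 0.00974, camera; adjusted p = 0.355 with an estimated correlation). Without the control library the median was 0.267 (adjusted p = 0.164), and the list did not pass at 1000 UMIs per cell either. Idi1 rose by 0.67 ± 0.18 (log2, SE; adjusted p = 0.0129, edgeR), Hmgcs1 by 0.88 ± 0.25 (adjusted p = 0.021), Fdps by 0.77 ± 0.22 (adjusted p = 0.0259), Ldlr by 0.81 ± 0.25 (adjusted p = 0.0473) and Il4i1 by 0.78 ± 0.09 (adjusted p = 1.21e-10). Srebf2 (0.33 ± 0.21, adjusted p = 0.487) and Hmgcr (0.19 ± 0.21, adjusted p = 0.737) did not pass. MHC class I genes rose in 3 of 11 members (7 adjusted over the list alone; median 0.251, adjusted p = 2.31e-05; adjusted p = 0.274 with an estimated correlation), and 96 genes rose and 26 fell of 2763. No other list passed, with costimulation (0.043) and MHC class II (0.208) nearest at adjusted p = 0.0708.

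The main comparison of the design asked how the sorted fraction of tumor-draining nodes differed from that of non-draining nodes. In all cells together, genes of the mregDC-like class led the rise: Ccl22 (ENSMUSG00000031779, chromosome 8, 94745590 to 94751699) stood at 352 and 270 CPM in draining against 82 and 73.1 in non-draining nodes and 89.9 in the control, and Ccl17 at 96.6 and 74 against 27.7 and 22.8. Fabp5, a fatty acid carrier, stood at 518 and 1060 CPM against 116 and 375, and the metallothionein Mt1 at 128 and 158 against 37.3 and 75.5. Cd80, Cd86 and Cd70, ligands that activate T cells, rose too. Siglech, a receptor of plasmacytoid DCs, fell from 1080 and 688 to 508 and 358 CPM, Xcl1, a chemokine of lymphocytes that attracts cDC1, from 173 and 345 to 66.2 and 140, and Clec10a, a lectin of cDC2, fell as well. The summed mregDC markers moved with these genes (7670 and 6250 CPM against 3320 and 5160), as did those of plasmacytoid DCs (3730 and 3270 against 7400 and 5050).

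With the barcode set as a block, 237 genes rose and 245 fell of 12205 (482 in all; 179 by DESeq2). Ccl22 rose by 2.04 ± 0.1 (log2, SE; adjusted p = 1e-04, edgeR), Crispld2, a secreted protein, by 2.34 ± 0.15 (adjusted p = 0.000408), Ccl17 by 1.8 ± 0.11 (adjusted p = 0.00027), Fabp5 by 1.88 ± 0.14 (adjusted p = 0.000755) and Mt1 by 1.46 ± 0.15 (adjusted p = 0.00383). Cd63 rose by 1.08 ± 0.16 (adjusted p = 0.00846) from 46.3 and 123 to 125 and 194 CPM, with 174 in the control. Siglech fell by 0.97 ± 0.09 and Xcl1 by 1.29 ± 0.1 on the log2 scale. Costimulation genes rose in 8 of 12 members (11 adjusted over the list alone; median 0.813, adjusted p = 7.92e-22; adjusted p = 0.834 with an estimated correlation), and tolerance genes, among them Fas and Cd200, in 8 of 18 (10 adjusted over the list alone; 0.608, adjusted p = 1.75e-09; adjusted p = 0.834 with an estimated correlation). Unfolded protein response genes fell in 2 of 11 (Xbp1 and Hsp90b1; 8 adjusted over the list alone; -0.309, adjusted p = 0.00011; adjusted p = 0.842 with an estimated correlation). NF-kB genes split, with 2 up (Traf1, Nfkbia) and 2 down of 16 (8 and 2 adjusted over the list alone; median 0.311, adjusted p = 0.0118; adjusted p = 0.842 with an estimated correlation).

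Cholesterol synthesis genes passed weakly in all cells, with Idi1 alone rising of 20 (3 adjusted over the list alone; median 0.114, adjusted p = 0.0439; adjusted p = 0.842 with an estimated correlation). Idi1 rose by 0.61 ± 0.11 (adjusted p = 0.0165), while Srebf2 (-0.03 ± 0.1), Hmgcr (0.07 ± 0.12) and Ldlr (-0.01 ± 0.15) did not pass (adjusted p = 0.921, 0.854 and 0.981). The other lists did not pass: SREBF2 regulation and uptake (median -0.149, adjusted p = 0.0667), fatty acid synthesis (-0.081, 0.465), cholesterol efflux (0.012, 0.709), glycolysis (0.037, 0.96), interferon (0.168, 0.575), MHC class I (-0.022, 0.961) and MHC class II (-0.131, 0.118). In the planned fit without a block, edgeR called 0 genes of 12904, with 350 at an unadjusted p under 0.05 and 6 by DESeq2. There costimulation (0.81, adjusted p = 3.69e-23), tolerance (0.623, adjusted p = 2.01e-07), unfolded protein response (-0.304, adjusted p = 0.00523) and NF-kB genes (0.296, adjusted p = 0.0391) passed, and cholesterol synthesis genes did not (0.121, adjusted p = 0.227). With an estimated correlation these adjusted p values were 0.206, 0.206, 0.311, 0.769 and 0.968.

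Within the mregDC-like class the question was whether the cells themselves differed by node, beyond their number. Cd80 and Cd86, ligands that activate T cells, and Cd200 rose in draining nodes. Cd80 (ENSMUSG00000075122, chromosome 16, 38455561 to 38496335) stood at 59.7 and 53.5 CPM in draining against 20.7 and 5.67 in non-draining nodes and 10.2 in the control. Cd86 (ENSMUSG00000022901, chromosome 16, 36603869 to 36666081) stood at 127 and 190 CPM against 47.6 and 68, with 68.7 in the control, and Cd200, an inhibitory ligand of myeloid cells (ENSMUSG00000022661, chromosome 16, 45382135 to 45409053), at 219 and 169 against 45.5 and 86, with 90.9 in the control. Stat4, a transducer of interleukin 12 signals, and Gapdh, a glycolytic enzyme, rose too. The interferon-induced genes Rsad2 and Mx1 fell, from 22.8 and 50.1 to 8.4 and 16.6 CPM and from 128 and 290 to 75.2 and 170, as did the nuclease gene Dnase1l3. B cell genes such as Cd79a fell alongside, from 110 and 51 to 13.3 and 14.9 CPM, and the summed B cell markers were 176 and 155 CPM in draining against 886 and 491 in non-draining nodes, with 280 in the control.

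With the barcode set as a block, 28 genes rose and 33 fell of 8414 (61 in all; 9 by DESeq2). Cd80 rose by 2.36 ± 0.37 (log2, SE; adjusted p = 0.00516, edgeR), Cd86 by 1.46 ± 0.19 (adjusted p = 0.00154) and Cd200 by 1.45 ± 0.23 (adjusted p = 0.00516). Myl7, a cardiac myosin light chain gene that leads cluster 7, rose by 5.34 ± 0.68 (adjusted p = 0.0011), and Gapdh by 0.75 ± 0.14 (adjusted p = 0.0189). Rsad2 fell by 1.53 ± 0.31, Mx1 by 0.76 ± 0.16 and Dnase1l3 by 1.26 ± 0.2 on the log2 scale. Interferon genes fell in 2 of 17 members (4 adjusted over the list alone), were lower in 15, and passed as a list (median -0.518, adjusted p = 4.97e-06; adjusted p = 0.581 with an estimated correlation). Tolerance genes rose in 1 of 13 (3 adjusted over the list alone; 0.236, adjusted p = 0.00744; adjusted p = 0.581 with an estimated correlation). Costimulation genes rose in 2 of 11 (Cd80 and Cd86; 3 adjusted over the list alone), and their test pointed up (adjusted p = 0.00744; adjusted p = 0.581 with an estimated correlation) with a mean of 0.547 but a median of -0.048. MHC class I genes were lower in 11 of 12 members, 0 by their own test (1 adjusted over the list alone; -0.26, adjusted p = 0.00112; adjusted p = 0.581 with an estimated correlation), and unfolded protein response genes also passed (-0.268, adjusted p = 0.0147; adjusted p = 0.581 with an estimated correlation).

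The cholesterol program did not differ detectably by node within the class. Cholesterol synthesis genes were higher in 8 and lower in 11 of 19 members (median -0.178, adjusted p = 0.906), and Srebf2 (-0.31 ± 0.19, adjusted p = 0.613), Hmgcr (-0.46 ± 0.2, adjusted p = 0.456), Ldlr (-0.57 ± 0.22, adjusted p = 0.349) and Cd63 (-0.12 ± 0.13, adjusted p = 0.817) did not pass. Nor did SREBF2 regulation and uptake (-0.237, adjusted p = 0.372), fatty acid synthesis (-0.147, 0.36), cholesterol efflux (-0.116, 0.906), glycolysis (0.006, with a mean of -0.109; 0.829), MHC class II (0.01, 0.372) or NF-kB genes (-0.113, 0.741). Without a block, edgeR called 0 of 9836 genes, with 234 at an unadjusted p under 0.05 and 1 by DESeq2. There the interferon (-0.501, adjusted p = 1.91e-05), costimulation (median 0.042, mean 0.747, adjusted p = 0.00188) and tolerance lists (0.193, adjusted p = 0.0468) passed, and adjusted p = 0.672 with an estimated correlation for each. The class's largest cluster was cluster 7 in draining replicate 1 (42%), cluster 8, led by Mfge8, in non-draining replicate 1 (31.9%) and cluster 2 in both replicate 2 libraries (41.1% and 63.2%) and the control (77.4%), so cells of different clusters were compared.

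**Figure D3:**
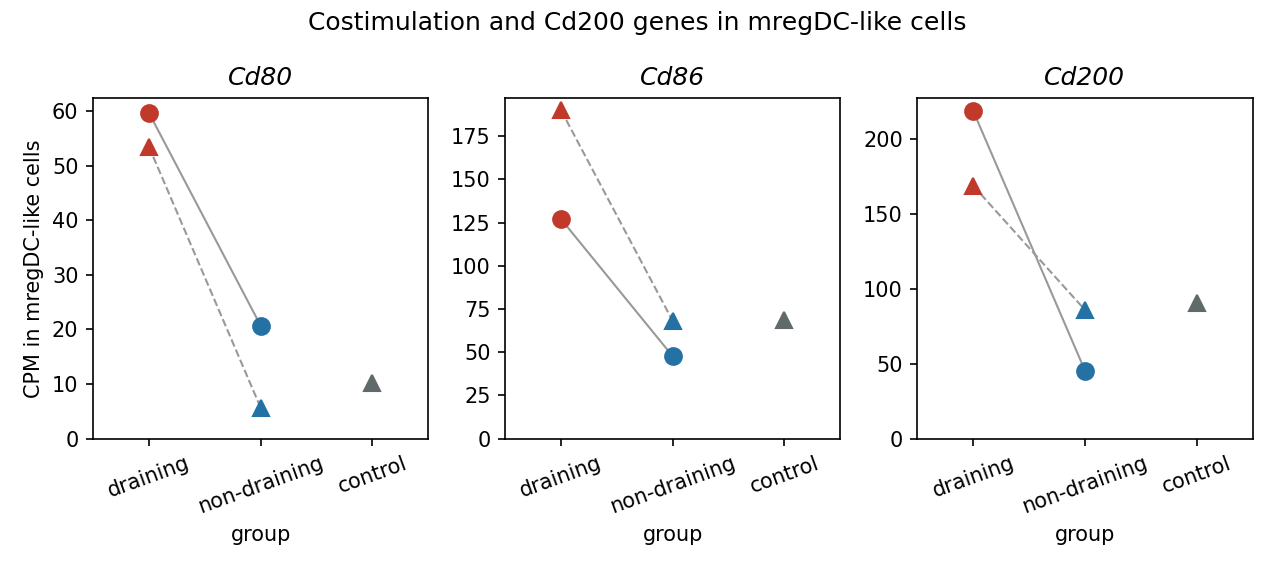
CPM (y axis) of Cd80, Cd86 and Cd200 in the summed mregDC-like cells of each library (x axis, by node), with circles and solid lines for the barcode set of both replicate 1 libraries and triangles and dashed lines for the other set, which includes the control. Each gene was higher in the draining than in the non-draining library of its set, as for Cd86 with 127 against 47.6 and 190 against 68.

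The same comparison was made in the other conventional DC classes. In cDC2-like cells Fabp5, Id2, a regulator of DC development, and Ltb, a lymphotoxin chain that shapes lymphoid tissue, rose in draining nodes, and Idi1 stood at 16 and 59 CPM against 5.58 and 20. Cd8b1, a T cell coreceptor chain, Lig1, a DNA ligase of replication, and Runx2, a factor of plasmacytoid DCs, fell. The summed plasmacytoid markers in this class were 1410 and 827 CPM in draining against 2140 and 1570 in non-draining nodes, and the proliferation genes 681 and 509 against 1120 and 563. In cDC1-like cells Pclaf, a replication factor, rose from 56.2 and 84.4 to 127 and 193 CPM, where proliferation genes summed to 1420 and 1820 against 971 and 1570.

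With the block, 28 genes rose and 40 fell of 6597 in cDC2-like cells (1 by DESeq2), and 1 rose and 1 fell of 8152 in cDC1-like cells (1 by DESeq2). In cDC2-like cells Fabp5 rose by 0.84 ± 0.15 (log2, SE; adjusted p = 1.34e-05, edgeR), Id2 by 0.98 ± 0.2 (adjusted p = 0.000327) and Idi1 by 1.57 ± 0.42 (adjusted p = 0.0256). Cd8b1 fell by 3.27 ± 0.37 and Runx2 by 1.33 ± 0.26 on the log2 scale. In cDC1-like cells Pclaf rose by 1.24 ± 0.13 (adjusted p = 0.038); it was a leading gene of the cycling cluster 27, which held 9.6% and 13.4% of the class in draining and 4.2% and 9.8% in non-draining nodes. Costimulation genes passed in cDC2-like cells (median 0.453, adjusted p = 0.0383; adjusted p = 0.845 with an estimated correlation), and unfolded protein response genes in cDC1-like cells (-0.329, 0 called and 5 adjusted over the list alone; adjusted p = 1.31e-06; adjusted p = 0.894 with an estimated correlation). MHC class I genes also passed in cDC1-like cells (-0.089, adjusted p = 0.0451; adjusted p = 0.894 with an estimated correlation). Cholesterol synthesis genes did not pass in cDC2-like (0.137, adjusted p = 0.264) or cDC1-like cells (0.122, adjusted p = 0.232). Without a block edgeR called 0 genes in both, with 102 of 7661 and 78 of 9664 at an unadjusted p under 0.05 and 0 by DESeq2. In the cDC2-like fit with the block, the spread was taken as equal for all genes of a given abundance, so its adjusted p values rest on that.

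The control node asked what distinguished either node of tumor-bearing mice from that of tumor-free mice. The control mice were wildtype, so genotype and tumor were not separated, and non-draining nodes also differed from the control in site. The control is 1 library and adds no spread, and the fits with the barcode set as a term had 1 residual degree of freedom. Cxcl10, an interferon-induced chemokine, stood at 67.8 CPM in the control against 2.98 and 22.2 in draining and 5.2 and 14.3 in non-draining nodes. Gzmc, a granzyme of killer and innate lymphoid cells, stood at 12.9 CPM in the control against 53.1 and 195, and 204 and 393. Genes of plasmacytoid DCs (Klk1, Cox6a2) and of MHC class II (H2-Ab1) were lower in draining nodes than in the control, and Igfbp4 and Lef1, genes of naive T cells, higher. Summed plasmacytoid markers were 9530 CPM in the control and T cell markers 863, against 1410 and 2700 in draining and 1330 and 2000 in non-draining nodes. Over all cells, this mix was not separated from changes within cells. With the barcode set as a term, the MHC class II list median was -0.627 in draining and -0.479 in non-draining nodes over all cells. Within mregDC-like cells it was -0.029 and -0.052, and within cDC1-like cells of draining nodes 0.004.

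With the barcode set as a term, chosen after the data were seen, 751 genes rose and 927 fell in draining nodes (503 in all by DESeq2), and 644 rose and 633 fell in non-draining nodes (217 by DESeq2), of 12904. Cxcl10 fell by 1.83 ± 0.23 (log2, SE; adjusted p = 6.23e-05, edgeR) and 2.09 ± 0.25 (adjusted p = 9.9e-05), Irf7, a driver of interferon production, fell by 1.36 ± 0.17 in draining nodes, and Gzmc rose by 3.66 ± 0.25 and 5.07 ± 0.26. Apoe, a lipid carrier, rose by 1.59 ± 0.17 in each. Crispld2 (fell by 1.24), Fabp5 (fell by 1.23), Cd63 (fell by 0.78) and Cd80 (fell by 1.04) were lower in non-draining nodes than in the control. Unfolded protein response genes fell in 8 of 11 members in draining nodes (-0.714, adjusted p = 1.58e-05; adjusted p = 0.71 with an estimated correlation), MHC class II genes in 8 of 12 (-0.627, adjusted p = 1.58e-05; adjusted p = 0.71 with an estimated correlation), and costimulation genes rose in 6 of 13 (0.527, adjusted p = 0.000182; adjusted p = 0.71 with an estimated correlation). In non-draining nodes MHC class II genes fell in 9 of 12 members (-0.479, adjusted p = 0.000421), unfolded protein response genes in 3 of 11 (6 adjusted over the list alone; -0.312, adjusted p = 0.024) and tolerance genes in 4 of 19 (6 adjusted over the list alone; -0.412, adjusted p = 0.00369). Interferon genes fell there in 5 of 24 and rose in 1 (7 and 1 adjusted over the list alone; -0.287, adjusted p = 0.00376), and fatty acid synthesis genes rose in 3 of 14 (0.413, adjusted p = 0.00279), with adjusted p = 0.663 with an estimated correlation for each of these 5 lists. Costimulation genes did not pass in non-draining nodes (-0.374, adjusted p = 0.0551), nor interferon genes in draining nodes (-0.273, adjusted p = 0.0502), where they passed without the term (-0.563, adjusted p = 2.39e-06; adjusted p = 0.686 with an estimated correlation). Cholesterol synthesis genes did not pass in draining (0.212, adjusted p = 0.227) or non-draining nodes (0.036, with the test leaning down; adjusted p = 0.972). Without the term, edgeR called 0 genes in both, with 606 and 407 at an unadjusted p under 0.05 and 21 and 10 by DESeq2.

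In mregDC-like cells against the control, Apoe rose by 3.1 ± 0.35 (log2, SE; adjusted p = 9.39e-05, edgeR) in draining and 2.4 ± 0.41 (adjusted p = 0.0184) in non-draining nodes, from 6.32 CPM in the control to 35.4 and 59.1, and 31 and 30.2. Apoe was also the leading gene of the macrophage-like cluster 29 and of cluster 30, which together held 0.54% and 4.15% of the cells of draining, 0.67% and 2.67% of non-draining and 0.5% of control nodes. C1qa, another leading gene of both, was at 3620 CPM in cluster 29 (Apoe 25100), and in mregDC-like cells at 0.442 and 2.12 CPM in draining, 4.14 and 0.945 in non-draining and 1.37 in control nodes. Cd80 and Cd86 rose in draining nodes by 2.26 ± 0.35 and 1.43 ± 0.21, where Isg15 and Ifi27l2a, interferon-induced genes, fell by 1.88 ± 0.24 and 1.75 ± 0.25. Cxcl1, which attracts neutrophils, and Serpinb9b, a protease inhibitor, fell in both, from 36 and 54.9 CPM in the control to 8.5 or less and 12.4 or less. Il12b, a subunit of interleukin 12, and Dnase1l3 rose in non-draining nodes. In all, 44 genes rose and 33 fell in draining nodes of 9836 (1 by DESeq2), and 7 rose and 2 fell in non-draining nodes (0 by DESeq2, with 621 at an unadjusted p under 0.05 in edgeR). Without the term edgeR called 0 genes in both, with 226 and 132 at an unadjusted p under 0.05.

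Sex-linked and melanocyte genes were read in all cells. Ddx3y, a Y-linked gene, stood at 51.1 to 60 CPM and Xist, expressed from the inactive X chromosome, at 1 count or fewer in all 5 libraries. The melanocyte enzymes Tyr, Tyrp1 and Dct had 0 counts in all 5 libraries, which allows up to 3 counts per library, and Pmel had 13 or fewer, most in the control. Genes of dissociation stress, such as Fos and Jun, summed to 1320 and 1840 CPM in draining, 1290 and 1810 in non-draining and 1800 in control nodes, a difference that followed the barcode set.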

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

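All tests weighed here had their expected outcomes written before their results were seen. Taking only the splits that part both sums of each library, reading the clusters library by library and comparing matched draws on the same genes were chosen afterwards. The patterns were found in the same data, so what follows are hypotheses. Testing whether the node effect differed between classes was planned.

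Cholesterol synthesis genes were higher in mregDC-like cells than in cDC2-like and cDC1-like cells. Each of the 5 libraries gave both sums, most of the 126 splits put both sums of some library on one side, and only 16 part all 5 pairs as the real one does, too few for a share under 0.05; 1 called as many members (the real one, with 15) and the highest of the others 0, in both comparisons. That one cluster of the class carries the genes was argued against, since the list's median log2 ratio to cDC2-like cells, pooled over libraries, was over 0.5 in 5 of 5 mregDC-like clusters; in the libraries with at least 20 cells of a cluster it ran from 0.48 to 1.65 in clusters 2, 7, 8 and 17, and from 0.15 to 0.87 in cluster 26, which stays open. RNA from other cells and the mix of barcode sets were not tested, though each library gave both classes. A higher demand for sterols in mature DCs may account for it and stays among the open explanations, since no test here separated it from a difference in maturation.

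mregDC-like cells with a Cd63 UMI had more RNA of cholesterol synthesis genes than those without as a list, with 3 of 8 members called. The list call was lost with an estimated correlation (adjusted p = 0.355), without the control (adjusted p = 0.164) and at 1000 UMIs per cell. Only 16 of the 126 splits part the sums of all 5 libraries as the real one does, too few for a share under 0.05; 1 called as many members (the real one, with 3) and the highest of the others 0. The mix of mregDC-like clusters stays open: with cells matched on library and cluster, the median log2 ratio ran from 0.103 to 0.59 over 20 draws with a middle of 0.276, against 0.457 unmatched, and 4 draws passed the list test. Matching left fewer cells and 5 to 7 genes in place of 8, so these medians cover different genes; on the same genes 19 of 20 draws stayed over 0.5 of the unmatched median, and Idi1 ran from 0.43 to 0.83 against 0.67. A link between Cd63 and cholesterol synthesis in the same cells may exist but is not shown.

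Cd80, Cd86 and Cd200 were higher in mregDC-like cells of draining than of non-draining nodes. Without cluster 7, Cd80 went from 2.36 ± 0.37 to 2.46 ± 0.51 (log2, SE; adjusted p = 0.149), Cd86 from 1.46 ± 0.19 to 0.92 ± 0.26 (adjusted p = 0.541) and Cd200 from 1.45 ± 0.23 to 0.62 ± 0.25 (adjusted p = 0.738); the calls ended with larger errors for all 3 and smaller changes for Cd86 and Cd200. The smallest change, 0.62, lay between the bounds set. The mix of mregDC-like clusters may therefore account for part of the pattern and cannot be told apart from a change within cells. The estimate shrank most for Cd200. Without cluster 7, Cd80 went from 59.7 and 53.5 to 20.7 and 24.2 CPM in draining nodes. In non-draining nodes it went from 20.7 and 5.67 to 4.6 and 3.8. Much of its RNA thus lay in cluster 7, and its ratio without that cluster rests on low values. The class markers could not decide whether RNA from B cells thinned the class's own RNA. The 14 class markers had a median change of 0.003 with 7 up and 7 down. But TMM normalization takes out a change shared by most genes of the class, so such thinning could not show there. B cell markers summed to 886 and 491 CPM in mregDC-like cells of non-draining replicates 1 and 2, and to 2420 and 2700 over all cells. Of all kept UMIs there, B cell-like cells gave 436396 of 10188981 and 797105 of 8478304. B cell RNA was thus a small part of the class's RNA. This argues against thinning as the source of changes as large as those of Cd80, Cd86 and Cd200. The site of the node, inguinal against axillary, and the tumor's drainage were not separated.

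The other results here are genes and lists whose node effect differed between classes by an interaction test in edgeR (log2, SE), with 406 of 7807 genes against cDC2-like and 424 of 9419 against cDC1-like cells at an unadjusted p under 0.05. Dnase1l3, a nuclease (ENSMUSG00000025279), changed by -2.19 ± 0.31 (adjusted p = 0.0112) more in mregDC-like than in cDC2-like cells, from 68.6 and 67.6 CPM in draining against 120 and 204 in non-draining nodes in the first class and 79.8 and 75.8 against 34.9 and 50 in the second. Unfolded protein response genes had a median of -0.39 in the same test (adjusted p = 0.003, camera; adjusted p = 0.826 with an estimated correlation). Against cDC1-like cells the immunoglobulin genes Iglc1 (-5.49 ± 0.67, adjusted p = 1.51e-05) and Ighd (-2.84 ± 0.51, adjusted p = 0.0157), which fall outside the rule for named genes, had a lower node effect. In mregDC-like cells Iglc1 stood at 1.33 and 2.97 CPM in draining and 163 and 11.3 in non-draining replicates 1 and 2. In cDC1-like cells it stood at 1.12 and 27.1 against 19.9 and 1.02, so its change there went opposite ways by replicate. Atp1b1, a subunit of the sodium pump, differed by 3.06 ± 0.57 (adjusted p = 0.0183), with 34.5 and 32.7 CPM against 14.5 and 12.3 in mregDC-like and 11.5 and 1.04 against 31.7 and 24.4 in cDC1-like cells. Interferon genes had a median of -0.433 (adjusted p = 0.0179; adjusted p = 0.748 with an estimated correlation). Cholesterol synthesis genes did not pass in either test (-0.095, adjusted p = 0.693, and -0.184, adjusted p = 0.198). DESeq2 called 0 genes in each, as did the fit on classes by marker score. Against cDC2-like cells the call of Dnase1l3 also ended with no cell filter and at Leiden resolution 2.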

How the results depend on the processing

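The barcode set as a term was chosen after the data were seen and all other alternatives before. Of 180 alternative values for the 15 designed results, 128 stayed the same, 43 moved, 4 newly passed and 5 no longer passed. Counts of genes and clusters stayed the same within 1.5-fold, and the share within the pooled SD between replicates (3.98 points). Lists and genes stayed the same on 1 side of the threshold, a change of direction counting only where a value passed. Of 2188 values for 176 named genes and other lists 1958 stayed the same, 126 newly passed, 101 no longer passed and 3 reversed. The reversed one was the median of costimulation genes in mregDC-like cells between nodes, 0.042, which became -0.048 with the block, -0.023 without the control and -0.151 without draining replicate 1 (range -0.151 to 0.32 with a library left out), while the test stayed up (adjusted p = 0.00744, 0.0145 and 0.0335; adjusted p = 0.581, 0.608 and 0.925 with an estimated correlation); the cause was not tested.

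For draining against non-draining nodes without a block (0 calls), DESeq2 called 6 genes over all cells and 1 in mregDC-like cells. Against the control it called 21 (draining) and 10 (non-draining). The replicate block called 482 genes over all cells, 61 in mregDC-like, 2 in cDC1-like and 68 in cDC2-like cells. The barcode set as a term called 1678 and 1277 against the control. No low-count filter gave 19 in mregDC-like, 5 in cDC1-like and 8 in cDC2-like cells. Leaving out each library gave 0 to 19 in mregDC-like cells (13 without draining replicate 1, 19 without draining replicate 2) and 0 to 2 in cDC2-like cells, and 0 over all cells. The cause was not tested, except that the block takes out the difference between barcode sets by construction.

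Genes whose node effect differed between classes were 1 against cDC2-like and 3 against cDC1-like cells. They became 0 and 0 by DESeq2, 22 and 12 with no low-count filter, 33 and 34 with the replicate as a block in each class, 4 and 1 with thinned counts, 0 and 1 with no cell filter, 7 and 21 with doublets removed, 0 and 16 at Leiden resolution 2 and 0 and 0 with classes by marker score. Leaving out a library gave 2 to 24 and 2 to 22 (24 without draining replicate 2, 22 without non-draining replicate 1). These counts moved under most settings and the cause was not tested.

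Cholesterol synthesis genes between nodes over all cells (median 0.121) newly passed with the block (0.114, adjusted p = 0.0439; adjusted p = 0.842 with an estimated correlation) and among the 3 conventional DC classes (0.247, adjusted p = 0.0105; adjusted p = 0.714 with an estimated correlation). They ran from -0.147 to 0.346 with a library left out, passing without draining replicate 1 (0.346, adjusted p = 0.00229; adjusted p = 0.677 with an estimated correlation). In mregDC-like cells they ran from -0.367 to 0.418, passing downward without draining replicate 2 (-0.367, adjusted p = 0.019; adjusted p = 0.704 with an estimated correlation). The class medians, 1.776 and 1.39, no longer passed with an estimated correlation (adjusted p = 0.369 and 0.332) and stayed past the threshold under all other settings run, from 1.649 to 1.891 and from 1.201 to 1.43. Between the Cd63 parts (0.457) the call was lost with an estimated correlation (adjusted p = 0.355), at 1000 UMIs per cell (0.267, adjusted p = 0.109) and without the control (0.267, adjusted p = 0.164; range 0.267 to 0.675). Ebp against cDC2-like cells lost its call without either draining library or non-draining replicate 2, and Cd86 against cDC1-like cells with no library block. The difference in mregDC-like share, 12.89 points, became 24.37 among the 3 conventional DC classes, as the denominator shrank. In simulation with the spread shared across genes, 98 (49%) of the genes changed 2-fold were recovered in mregDC-like cells with the block.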

Other observations

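The comparisons by class below that use the barcode set as a term, and the values by cluster or single library, were chosen after the data were seen.

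Interferon-induced genes were lower than in the control in the cDC2-like cells of tumor-bearing mice, at both sites. All 20 measured members were lower in draining and in non-draining nodes, with median log2 fold changes of -1.263 (adjusted p = 2.5e-28, camera; adjusted p = 0.411 with an estimated correlation) and -1.103 (adjusted p = 2.9e-20; adjusted p = 0.281 with an estimated correlation). In cDC1-like cells the medians were -0.797 (adjusted p = 3.18e-11; adjusted p = 0.679 with an estimated correlation) and -0.849 (adjusted p = 4.48e-11; adjusted p = 0.674 with an estimated correlation), where cluster 5 held 63.4% and 70% of the replicate 1 cells and 0.6% of the control, and cluster 16 held 2.1% and 4.2% against 62.2%. edgeR called 0 genes in these fits, with 101 and 180 of 7661 at an unadjusted p under 0.05 in cDC2-like and 227 and 339 of 9664 in cDC1-like cells. With the barcode set as a term, 10 and 8 of the 20 members fell in cDC2-like cells (12 and 10 adjusted over the list alone), and the medians were -0.958 and -0.79 (adjusted p = 6.64e-23 and 6.72e-19; adjusted p = 0.602 and 0.562 with an estimated correlation). In these cDC2-like fits edgeR called 194 and 366 genes in all and DESeq2 14 and 22, and the spread was taken as equal for all genes of a given abundance, so the member counts rest on that. Cells of different clusters were compared: cluster 13 held 44.6% of the cDC2-like cells of the control against 27.7% and 26.8% in draining and 22.9% and 12.3% in non-draining nodes, and cluster 12 held 24.8% against 39.4% and 48.2%, and 44.1% and 54.4%. With the library and the control brought to equal UMI totals, the list medians within cluster 12 were -3.49 to -1.41 (middle of 20 draws) in the 4 libraries, within cluster 13 -2.19 to -0.64 and within cluster 15 -0.87 to 0. The list was thus lower within cluster 12 (27 to 54 cells per library), and not in every library within cluster 15. Cluster 13, named on 3 of 14 markers, held 38 and 15 cells in draining and 27 and 7 in non-draining nodes. At Leiden resolution 2 its leading gene Ffar2 led an unnamed cluster with 96 control cells. Its leading genes S100a3 and Gal marked a cluster named mregDC-like with 65 control cells. The cDC2-like comparison with the control thus included cells whose name depends on the resolution, and it was not rerun at resolution 2. The replicate 2 sums of clusters 13 and 15 (14 and 19 cells in the latter) lay under the 20 cells asked elsewhere. In cluster 13 the draws of non-draining replicate 2 reached 0, while those of draining replicate 2 ran from -2.01 to -1.13 on 15 cells. As both lay under 20 cells, the list is read as lower in cluster 13 in replicate 1 alone. Monocyte and macrophage markers in this class summed to 2220 and 5640 CPM in draining, 3340 and 3870 in non-draining and 2480 in control nodes, and RNA or cells of that kind were not separated from it. In cDC1-like cells the list no longer passed (-0.438, adjusted p = 0.147, and -0.428, adjusted p = 0.0878), nor did it in the plasmacytoid class (0.301, adjusted p = 0.0561, and 0.123, adjusted p = 0.463). In mregDC-like cells, with the term, it passed in draining nodes (-0.49, 16 of 19 lower, 2 fell and 5 adjusted over the list alone; adjusted p = 6.3e-07; adjusted p = 0.543 with an estimated correlation). It did not in non-draining nodes, where the median was 0.142 while the test leaned down (adjusted p = 0.781). The control is 1 library of wildtype mice, so that library, the genotype and the absence of a tumor were not separated.

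Cholesterol synthesis genes were higher in the plasmacytoid DC-like cells of both replicate 2 libraries of tumor-bearing mice than in those of the control, which shares their barcode set. Library by library, the median log2 ratio of the 20 genes to the control was 0.61 and 0.41 in draining and non-draining replicate 2 (19 and 18 higher), but -0.17 and 0.03 in replicate 1 (8 and 11 higher). Idi1 stood at 67.7 and 59.8 CPM in replicate 2 and 19.3 and 21.3 in replicate 1, against 43.4 in the control. Nearly all plasmacytoid cells of replicate 1 fell in cluster 1 (99.3% and 99.8%) and those of the other 3 libraries in cluster 0 (93.9%, 96.5% and 96.5%), so the rise rests on 1 library per site. Without a term the medians were 0.365 in draining (16 of 20 higher, adjusted p = 0.00542; adjusted p = 0.664 with an estimated correlation) and 0.292 in non-draining nodes (14 of 20 higher, adjusted p = 0.00749; adjusted p = 0.766 with an estimated correlation). With the barcode set as a term they were 0.518 (19 of 20 higher, adjusted p = 2.91e-07; adjusted p = 0.731 with an estimated correlation) and 0.42 (18 of 20 higher, adjusted p = 4.43e-05; adjusted p = 0.768 with an estimated correlation), where 0 and 1 members passed their own test (6 and 5 adjusted over the list alone; edgeR called 73 and 132 genes of 9244 in all, with 755 and 1295 at an unadjusted p under 0.05, and DESeq2 5 and 8). Between draining and non-draining nodes the list did not pass in this class (0.081, adjusted p = 0.715). In the other classes the list did not pass without a term in draining nodes (0.321, adjusted p = 0.306, in cDC1-like, 0.096, adjusted p = 0.748, in cDC2-like and -0.127, adjusted p = 0.56, in mregDC-like cells). With the term it passed there in cDC1-like (0.557, 13 of 17 higher, adjusted p = 0.00488; adjusted p = 0.615 with an estimated correlation) and cDC2-like cells (0.431, 9 of 12 higher, adjusted p = 0.0252; adjusted p = 0.602 with an estimated correlation), where 0 and 1 members rose (1 and 1 adjusted over the list alone), and not in mregDC-like cells (0.241, adjusted p = 0.153). In the 3 conventional DC classes together 5 of 20 rose (7 adjusted over the list alone; 0.609, adjusted p = 9.57e-07; adjusted p = 0.413 with an estimated correlation), against 0.363 without the term (adjusted p = 0.11). In non-draining nodes none of these passed with the term (0.293, 0.106, 0.218 and, together, 0.239; adjusted p = 0.181, 0.269, 0.316 and 0.11).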
